A study of Mus musculus with 14 samples.

How the data were processed

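Mouse tumor-derived cells of the C57BL/6 strain at passages 6 to 8 carried either a control guide RNA (sgControl) or a guide against Nsd3 (sgNSD3), a histone H3 lysine 36 methyltransferase. Per the labels, the 14 samples comprise 6 of total RNA, 3 per condition, and chromatin samples, 4 for H3K36me2, 2 for H3K27me3 and 2 for the IgG control. The labels do not name the tumor type, and nothing in them says that the 3 RNA samples of a condition came from separate cultures, so p-values measure the spread between these samples, which may be technical. The RNA samples carry the same chromatin extraction text as the other samples, so how the RNA libraries were made is not given in the sources used here. Replicate numbers below follow the sample titles. For sgNSD3 RNA replicates 1, 2 and 3, the descriptions and deposited columns bear the numbers 3, 1 and 2. The IgG sample titled sgNSD3 has a source label of sgControl, and both samples titled IgG carry an antibody label of H3K36me2. No value of an IgG library was available here, and whether IgG entered the deposited chromatin scores is not stated.

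Per the submitters' processing notes, HISAT2, featureCounts and DESeq2 were used with the mm10 build, with no versions, settings or order given. The RNA values are deposited on a log2 scale by the authors, and the file's header and values place them on the variance-stabilised scale of the authors' DESeq2. A gene with 0 reads sits at 8.45 in each library. Turning the values back through the closed form of that transform gave whole multiples of 1 step per library, within 0.05 of a whole number, for 100% of the values above 0. These recovered counts summed to between 20294828 and 21863833 per library. Divided by the size factors implied by the steps, they are called normalized counts here.

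The chromatin values are signed scores deposited by the authors for gene bodies, in 1 column for H3K27me3 and 2 columns for H3K36me2. The header does not say which libraries were set against each other or in which order, so no direction between the conditions was drawn from them. In each column the 30 commonest values all lay within 8e-06 of a lattice of whole multiples of 1 step minus whole multiples of another, where the same search over random values reached at most 7 of 30. The steps are not given, since more than 1 pair of steps reached 30 in one column. The columns hold no values per library, so the planned tests of H3K36me2 and H3K27me3 between the conditions were not run. There were 0 other value columns in either table.

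Tests, lists, named genes and alternatives were fixed before the data were examined, except where stated. RNA was tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean-variance trend) on the deposited log2 values, with Benjamini-Hochberg adjustment and a threshold of 0.05. The plan kept genes with a mean of at least 3 on the log2 scale, meaning about 8 normalized counts. Because the deposited scale starts at 8.45, the filter was applied as a mean of at least 8 normalized counts, which left 18278 of 55433 genes. Likewise the minimum for the genes with the largest changes became 32 normalized counts. The deposited scale compresses changes of low genes, so folds are ratios of mean normalized counts, and log2 folds with standard errors come from limma on log2(normalized count + 1), which understates the change of low genes.

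Of 28 gene lists, the 26 with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Named genes were Nsd3, the 12 largest rises and 12 largest falls on the deposited log2 scale among called genes whose conditions did not overlap (predicted symbols left out), and up to 4 called members per list with the largest change; a few genes that this rule takes are not reported here. For the chromatin scores the plan named the 8 highest and 8 lowest H3K36me2 genes, the 5 highest and 5 lowest H3K27me3 genes, and 6 genes at each end of the H3K36me2 values that also changed in RNA. The planned minimum levels could not be applied to scores, predicted symbols were left out here too, the H3K36me2 genes had to have the same sign in both columns, and the same ranking without mitochondrial genes was added after the values were seen. Gene positions and lengths came from the RefSeq table of the mm10 assembly. Of 22470 gene bodies, 21120 matched an RNA gene by symbol and 1085 by RefSeq record.

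The RNA test was tested on simulated counts. They were drawn for the real means and library sizes with a dispersion of 0.000467, the median within conditions, for both conditions. Changes were given to 200 genes with a real mean of at least 32 normalized counts. The 25 tested members of the glycolysis and hypoxia list were also raised 1.25-fold, and that list was called (camera adjusted p = 1.6e-101). In 1 such run of the 3 against 3 RNA comparison, 18263 genes were tested. Recovery in the right direction was 71.6% of 67 genes changed 1.25-fold, 89.6% of 67 changed 1.5-fold and 98.5% of 66 changed 2-fold. These rates do not cover genes under 32 normalized counts. In 20 such runs camera called 30 lists that had not been changed as lists, and in each of them 1 or 2 members were among the changed genes. A list call can therefore rest on very few members. In 20 runs with no change, 3 gave a called gene and 1 a called list. All simulated genes shared 1 dispersion, whereas real sgControl pairs differed more than real sgNSD3 pairs. Their chi-square of gene counts per degree of freedom was 1.89 to 2.56 and 1.27 to 1.31, respectively. The simulated gene rates therefore need not hold for the real test. Simulated genes varied independently, whereas the estimated correlation reached 0.656 in the real mitochondrial list. The simulated list rates therefore need not hold for the real lists. Alternatives covered the filter, normalization, variance model, library weights, a size threshold, the replicate block, each library left out, another pseudocount, voom on the recovered counts and the settings of camera. A correction for gene length and the removal of ribosomal, mitochondrial and small structured RNA genes were added after the data were seen. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for the lattice search and the plots.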

Results

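The data set compared mouse tumor-derived cells carrying a control guide RNA with cells carrying a guide against Nsd3, an enzyme that methylates histone H3 at lysine 36. RNA was measured in 3 libraries per condition, with recovered totals of 20294828 to 21863833 counts. Among pairs of sgNSD3 libraries the chi-square of gene counts per degree of freedom was 1.27 to 1.31, among sgControl pairs 1.89 to 2.56, and between conditions 3.66 to 4.69, so no pair agreed as closely as counting error alone would give, and none was merged. This measure covers counting error only and does not show that the libraries came from separate cultures. The most abundant RNA was Gm26917, a transcript of a ribosomal RNA locus, at a mean of 7.39% of counts in sgControl and 7.74% in sgNSD3. Col1a1 and Fn1, which encode collagen and fibronectin, came next, with means of 406390 and 349615 normalized counts.

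Nsd3 itself was higher, not lower, in the libraries labelled sgNSD3. Nsd3 (chromosome 8, 25601601 to 25719667, mm10) had 14611, 14444 and 14717 normalized counts in sgControl replicates 1, 2 and 3, and 22053, 22076 and 21900 in the libraries labelled sgNSD3. The means were 14590 ± 138 and 22010 ± 95.2 normalized counts (SD, n = 3 each; limma adjusted p = 5.79e-14), a 1.51-fold difference and a log2 fold of 0.59 ± 0.025 (SE). Gene-level RNA does not show whether an edit disrupts the protein. An edit also need not lower the RNA, so the Nsd3 level does not settle whether the labels are right. Conditions are therefore named below by the labels of their libraries, and each direction rests on those labels.

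**Figure D1:**
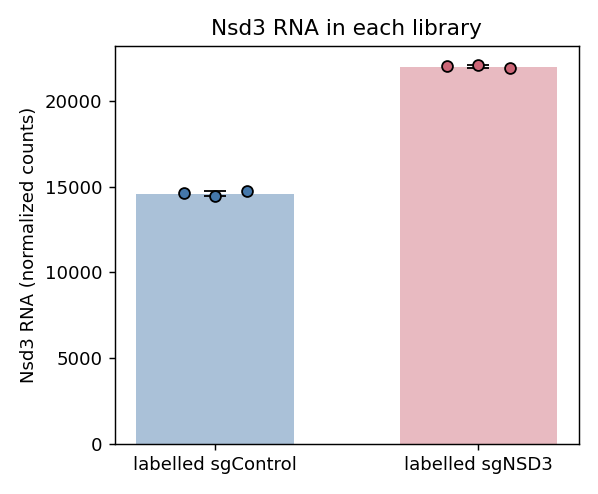
Nsd3 RNA in normalized counts (y axis) for the 3 libraries labelled sgControl and the 3 labelled sgNSD3 (points), with the mean (bar) and SD (error bar). The libraries labelled sgNSD3 lie between 21900 and 22076, above the sgControl libraries at 14444 to 14717.

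The largest rises on the deposited log2 scale in the libraries labelled sgNSD3 were found gene by gene, and the mesenchymal and matrix list was not called (camera adjusted p = 0.59, median log2 fold -0.01). Podn, a small proteoglycan, rose 4.83-fold, from 21.21 ± 3.1 to 102.4 ± 15.7 normalized counts (SD, n = 3). Adamts9, a secreted protease, rose 2.9-fold, Svep1, an adhesion protein, 2.87-fold, and Igfbp2, which binds insulin-like growth factors, 2.86-fold. The fibrillin genes Fbn2 and Fbn1 rose 1.92-fold and 1.41-fold, and Vcan, the proteoglycan versican, 1.65-fold, from 2383 ± 137 to 3935 ± 54.3 normalized counts. Rassf2 rose 2.78-fold, Rcan2 2.33-fold and Pkhd1l1 1.59-fold. Cebpb, a transcription factor, rose 1.63-fold, with a wide spread among sgControl libraries (1483 ± 492 normalized counts, SD). The limma adjusted p of these genes ranged from 5.88e-13 for Vcan to 3.28e-05 for Cebpb.

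The largest falls on the deposited log2 scale were short noncoding and mitochondrial RNAs together with a few protein-coding genes. Rn7sk, the RNA that restrains transcription elongation, was 1.63-fold lower, at 26480 ± 1390 against 43220 ± 4480 normalized counts (SD, n = 3). Rprl3 was 1.94-fold lower, and Rn7s2 and Rn7s1 were 1.54-fold and 1.4-fold lower. The mitochondrial genes mt-Nd2, mt-Nd1, mt-Nd4 and mt-Nd5 were 1.63-fold, 1.53-fold, 1.45-fold and 1.42-fold lower. Serpinb9, a granzyme inhibitor, was 1.53-fold lower, Vat1l 1.42-fold and Rab6b 1.72-fold. Krt19, a keratin of simple epithelia, fell 1.46-fold, from 3922 ± 278 to 2684 ± 27.9 normalized counts. The limma adjusted p of these genes ranged from 5.27e-12 for Serpinb9 to 0.000391 for Rn7s1. Near-identical copies of the small RNAs can share reads, so their values are uncertain.

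**Figure D2:**
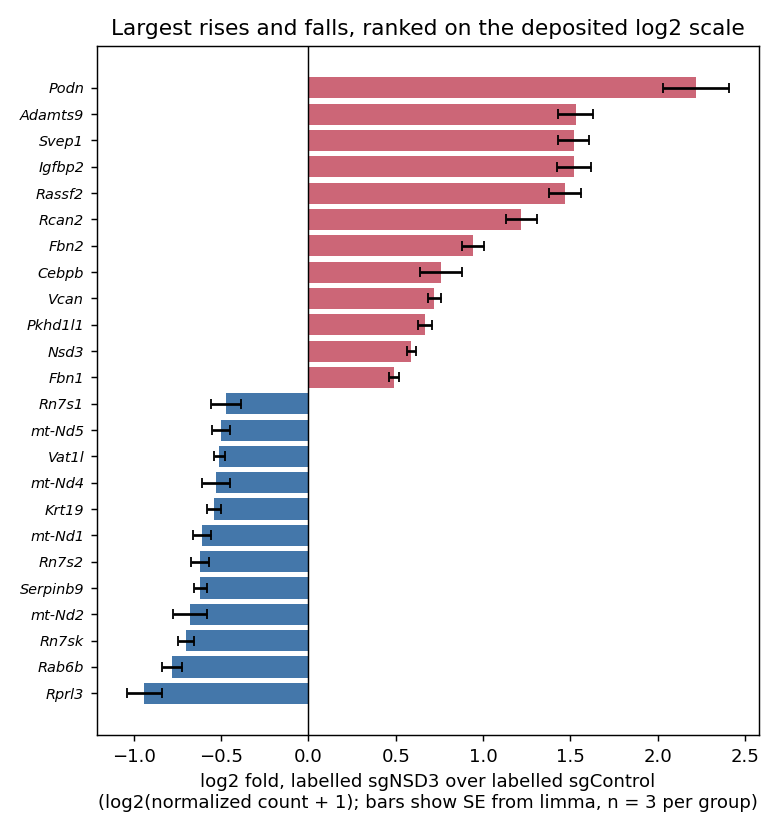
Log2 fold (x axis, log2(normalized count + 1), libraries labelled sgNSD3 over sgControl) of the 12 largest rises and 12 largest falls as ranked on the deposited log2 scale. Bars give the fold and error bars its SE from limma (n = 3 per condition), from -0.94 for Rprl3 to 2.22 for Podn.

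Of 18278 genes tested, 993 were higher and 1176 lower in the libraries labelled sgNSD3 (limma, adjusted p threshold 0.05), with a median absolute log2 fold of 0.26 among them. A log2 fold beyond 1 was reached by 88 of the higher and 75 of the lower genes. Since 1176 of all 18278 genes fell, some members of any list below could be called lower for that reason alone. The conditions did not overlap for 28.4% of genes, where chance gives 10%. Leaving out sgNSD3 replicate 1, 2 or 3 reduced the counts by over 1.5-fold, to 644, 641 and 658 higher and to 706, 727 and 774 lower.

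Genes of cholesterol synthesis and uptake were lower as a list (camera adjusted p = 1.8e-05), but not with an estimated correlation (adjusted p = 0.13). Of 22 measured, 8 fell and 1 rose, and 11 fell and 1 rose when adjusted over the list alone. Sc5d fell 1.2-fold, from 2589 ± 139 to 2162 ± 73.8 normalized counts (SD, n = 3). Msmo1 fell 1.21-fold and Cyp51 1.15-fold.

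Ribosomal protein and mitochondrial mRNAs were also lower as lists, but neither with an estimated correlation. Of 33 cytosolic ribosomal protein genes 14 fell and 0 rose, also when adjusted over the list alone, with Rps3 1.24-fold, Rps6 1.21-fold, Rps24 1.21-fold and Rpl6 1.14-fold lower (camera adjusted p = 2.4e-08, and adjusted p = 0.26 with an estimated correlation). Of 11 mitochondrially encoded mRNAs 8 fell, and 9 when adjusted over the list alone (camera adjusted p = 5.6e-10, and adjusted p = 0.23 with an estimated correlation). Counts were very uneven among these genes. The sgControl means were 124000 normalized counts for mt-Co1 but 174 for mt-Co2, 170 for mt-Co3 and 16.8 for mt-Nd4l. Why was not tested, and the counts may miss much of the mitochondrial mRNA. Beside these lists, reads counted for mitochondrial mRNA took 0.651%, 0.808% and 0.864% of counts in sgControl replicates 1, 2 and 3. In the libraries labelled sgNSD3 these reads took 0.654%, 0.674% and 0.637%. Transcripts of ribosomal RNA loci took 12.5%, 10.06% and 9.31% in sgControl and 11.09%, 10.93% and 10.98% in sgNSD3.

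Lists of MYC targets, of G2 and mitosis and of p53 targets were lower as well, but none of them with an estimated correlation. Of 57 MYC targets 7 fell, also when adjusted over the list alone, among them Myc itself (1.17-fold), Sord (423.7 to 338.9 normalized counts), Rrp9 (1.19-fold) and Npm1 (1.09-fold), with a camera adjusted p of 0.0013, and adjusted p = 0.13 with an estimated correlation. Of 24 G2 and mitosis genes 3 fell (Aurka 1.16-fold, Birc5 1.15-fold, Tpx2 1.09-fold; camera adjusted p = 0.014, and adjusted p = 0.23 with an estimated correlation). Of 21 p53 targets 5 fell, including the cell cycle inhibitor Cdkn1a (1.29-fold), Ccng1 (1.21-fold), Plk2 (1.15-fold) and Ei24 (1.12-fold; camera adjusted p = 0.014, and adjusted p = 0.23 with an estimated correlation). In both lists the counts were unchanged when adjusted over the list alone. Over all tested genes 1176 of 18278 fell, so the 3 falls among 24 G2 and mitosis genes are few beyond that share. Of 30 replication genes 4 fell, and 5 when adjusted over the list alone, with Pcna 1.13-fold lower, but the list was not called (camera adjusted p = 0.062). The G2 and mitosis list was lost without sgControl replicate 2 (adjusted p = 0.096), and the calls of Birc5 and Tpx2 without sgControl replicate 1 or any 1 of the sgNSD3 replicates. The call of Rrp9 was lost without sgNSD3 replicate 2 or 3.

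Of 16 genes of MHC class I antigen presentation 3 fell, also when adjusted over the list alone: B2m, the light chain of the complex, 1.28-fold, the peptide transporter Tap2 1.21-fold and the chaperone Calr 1.07-fold (camera adjusted p = 0.032, and adjusted p = 0.23 with an estimated correlation). Of 27 nuclear genes of oxidative phosphorylation 3 fell, and 4 when adjusted over the list alone, with the cytochrome c gene Cycs 1.49-fold and Atp5c1 1.14-fold lower (camera adjusted p = 0.038, and adjusted p = 0.69 with an estimated correlation). Of 17 heat shock and folding genes 3 fell (Pdia4 1.12-fold, Hspb1 1.13-fold, Hspa8 1.11-fold), and 4 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.048, and adjusted p = 0.39 with an estimated correlation). These lists also depended on single libraries: without sgControl replicate 2 the adjusted p was 0.065 for MHC class I, 0.44 for oxidative phosphorylation and 0.11 for heat shock. The MHC class I list was lost without sgControl replicate 1 as well, oxidative phosphorylation also without sgControl replicate 1 or sgNSD3 replicate 1 or 3, and heat shock without any library but sgControl replicate 3. The calls of Tap2 and Calr were each lost without any 1 of the sgNSD3 replicates.

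Only the Polycomb and the FGFR and MAPK feedback lists were called higher among the 26 lists, and neither with an estimated correlation (adjusted p = 0.23 each). Of 14 genes of Polycomb repressive complex 2 and H3K27 demethylases, 3 rose, and 6 when adjusted over the list alone. They were Phf19 (2.15-fold, from 9.037 ± 1.75 normalized counts, SD, n = 3), Suz12 (1.1-fold), a core subunit, and the demethylase Kdm6b (1.08-fold), which acts against the complex (camera adjusted p = 0.014). Of 19 FGFR and MAPK feedback genes 5 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.032). The immediate early genes Fosb (1.16-fold), Egr1 (1.14-fold) and Fos (1.12-fold), the cyclin Ccnd1 (1.14-fold) and Spred1 (1.11-fold) were higher. Phlda1 and Dusp6 were 1.18-fold and 1.07-fold lower. On ranks this list was not called (camera adjusted p = 0.099). The calls of all 3 Polycomb genes were lost when one of at least 3 libraries was left out, sgNSD3 replicates 1 and 2 among them. The FGFR and MAPK feedback list was lost without sgControl replicate 2 or sgNSD3 replicate 1 (adjusted p = 0.11 and 0.059). None of the 11 list calls held with an estimated correlation. By fry, which tests whether the genes of a list move one way on balance without comparing them with other genes, 7 of the 11 passed 0.05; the mitochondrial, ribosomal protein and heat shock lists (adjusted p = 0.063 each) and oxidative phosphorylation (adjusted p = 0.26) did not. Of the lists not called by camera 4 passed by fry, each lower: replication (adjusted p = 0.015), fibroblast markers (0.029), interferon response and squamous markers (0.044 each). For a change in either direction 25 of the 26 lists passed by fry.

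**Figure D3:**
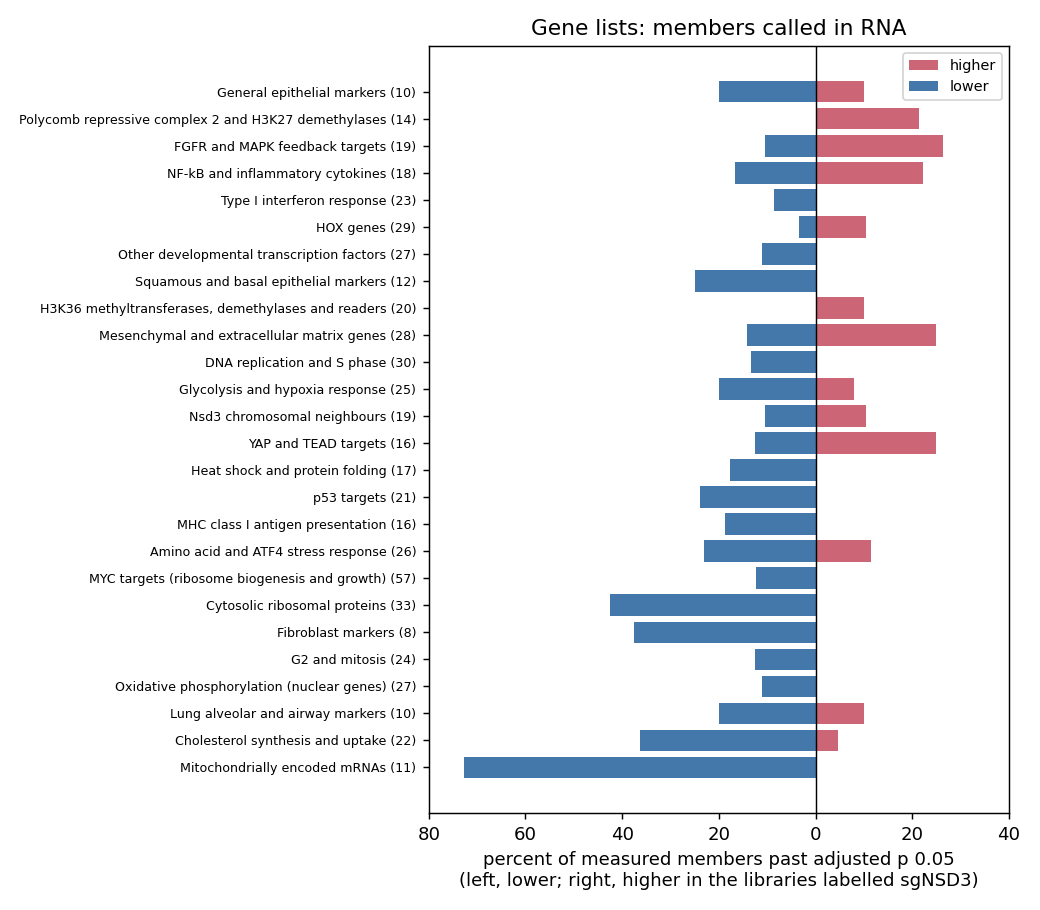
Percent of measured members (number in brackets) of each of the 26 gene lists called lower (left) or higher (right) in RNA of the libraries labelled sgNSD3, ordered by median log2 fold. Mitochondrially encoded mRNAs had 8 of 11 members lower, and 14 of 33 cytosolic ribosomal protein genes were lower.

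Several lists that were not called had members moving both ways. Of 28 mesenchymal and matrix genes 7 rose and 4 fell (9 and 7 when adjusted over the list alone; camera adjusted p = 0.59), with Fn1 1.27-fold higher. Under quantile normalization the log2 change of Fn1 on the deposited scale was 0.17 (adjusted p = 0.01) against 0.35 in the main test (adjusted p = 6e-08). Col1a1 was 1.13-fold higher in the main test and level under quantile normalization, and its call was lost without sgNSD3 replicate 1 or 2. Of 16 YAP and TEAD targets 4 rose and 2 fell (6 and 2 when adjusted over the list alone; camera adjusted p = 0.89), and Ccn2 was 1.32-fold lower while Crim1 was 1.17-fold higher. Of 18 inflammatory genes 4 rose and 3 fell (5 and 3 when adjusted over the list alone; camera adjusted p = 0.47), with the chemokine Cxcl1 1.44-fold higher and Ccl2 and Ccl7 1.26-fold and 1.28-fold lower. Of 26 amino acid response genes 3 rose and 6 fell (5 and 8 when adjusted over the list alone; camera adjusted p = 0.48), with the cystine transporter Slc7a11 1.43-fold higher. Of 25 glycolysis and hypoxia genes 2 rose and 5 fell (2 and 6 when adjusted over the list alone; camera adjusted p = 0.36), with the lactate transporter Slc16a3 1.45-fold higher and Pkm 1.15-fold lower. Of 20 H3K36 enzymes and readers 2 rose, also when adjusted over the list alone (camera adjusted p = 0.77): Ash1l 1.09-fold and Nsd1 1.07-fold, both calls being lost without sgControl replicate 2 or any 1 of the sgNSD3 replicates. Of 19 genes neighbouring Nsd3, 2 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.72), with Tacc1 1.26-fold higher and Zfp703 1.17-fold lower.

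For the chromatin marks, the authors' deposited table gives 1 signed score per gene body and column, without the libraries behind it, so no change between conditions can be read from it. In the authors' deposited table, 89.4% and 92.4% of 22470 gene bodies were above 0 in the H3K36me2 columns, with medians of 0.0757 and 0.125, against 31.5% and a median of -0.0258 for H3K27me3. Across 21995 gene bodies, mitochondrial genes and those at 0 in each column left out, Spearman's rho was 0.18 between the H3K36me2 columns of the authors' deposited table. It was -0.145 between their mean and H3K27me3, and -0.029 over the 13241 of these genes with tested RNA. Genes are not independent replicates, and no test was made.

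Rank correlation of the H3K36me2 scores with the RNA difference was near 0, while the share of genes with higher RNA climbed with the score. Across 13241 genes, Spearman's rho between the mean H3K36me2 score in the authors' deposited table and the RNA change was 0.014, and 0.053 for H3K27me3. RNA of the 500 genes with the highest and the 500 with the lowest H3K36me2 scores was not called different from that of other genes (camera adjusted p = 0.91 and 0.92). With genes matched on RNA level, 5 bins of H3K36me2 score held 2312 genes each. From the lowest bin to the highest, 4.58%, 5.02%, 6.1%, 6.31% and 8.39% were higher in RNA. In the same order, 7.4%, 8%, 7.7%, 8.35% and 7.61% were lower. These shares were not tested. The bins were not matched on gene length, along which higher calls also climbed, from 54 of the 3100 shortest genes to 422 of the 3100 longest. Of 10 bins without this matching, the highest had 124 genes with higher and 131 with lower RNA, and the lowest 63 and 87. The naming rule took only genes with higher RNA from the highest bin and with lower RNA from the lowest. The names below therefore do not show a link between score and RNA. Genes in the highest bin with higher RNA included Emilin2 (3.52-fold), Igfbp2, Rcan2, Vcan, Cebpb and Thbd (1.52-fold). Genes in the lowest bin with lower RNA included Tnfrsf21 (1.31-fold), B2m, Rps6, Rpsa-ps10 (1.36-fold), Krt14 (1.59-fold) and Cdc37 (1.19-fold).

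The highest H3K36me2 scores in the authors' deposited table belonged to mitochondrial genes, which carry no histones. In the authors' deposited table mt-Co1 had H3K36me2 scores of 4.2 and 10.5, and the 13 mitochondrial genes had medians of 3.55 and 9.59 for H3K36me2 and -1.77 for H3K27me3. Without them, the highest H3K36me2 scores in the authors' deposited table were 4.89 and 8.81. Gene bodies above 0 in both columns, with predicted symbols left out as well, were ranked by the mean of the columns after the values were seen. The authors' deposited table then placed Drg1 (3.86 and 4.59), Sfi1 (3.64 and 4.07) and Aida (2.28 and 5.11) highest for H3K36me2. Their H3K27me3 scores there were -0.515, -0.183 and -1.91, so Aida resembled the mitochondrial genes in both marks. Slc30a4 came next, at 1.12 and 0.47 for H3K36me2. Among gene bodies below 0 in both columns, again without predicted symbols, Hnrnpa0 (-0.179 and -0.0432) was lowest in the authors' deposited table. For H3K27me3 scores in the authors' deposited table ranged from -2.3 to 0.839. With predicted symbols left out, the authors' deposited table placed Cadm3 (0.699), Cbfa2t3 (0.582), Mkrn3 (0.562), Car10 (0.557) and Hba-a1 (0.553) highest. Nsd3, listed there under its older symbol Whsc1l1, had scores of 0.0517 and 0.0664 for H3K36me2 and -0.0268 for H3K27me3 in the authors' deposited table.

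**Figure D4:**
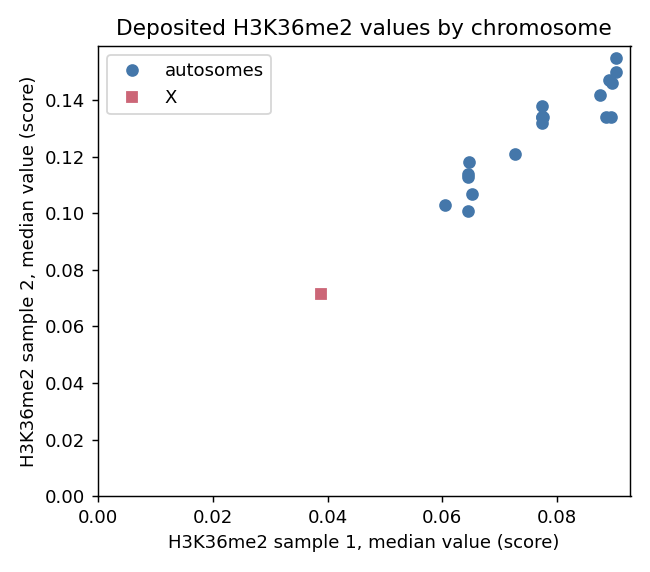
Median H3K36me2 score per chromosome in the authors' deposited table, sample 1 (x axis) against sample 2 (y axis), for 19 autosomes (circles) and X (square). X lies lowest, at 0.0388 and 0.0716.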

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

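The length correction, the removal of ribosomal, mitochondrial and small structured RNA genes, and the chromatin values for H3K36me2 against H3K27me3 other than the main one were chosen after the data were seen. Nsd3 kept its direction and adjusted p threshold in each RNA alternative except the size threshold, which was applied to log2(normalized count + 1), where its log2 fold of 0.59 lies under 1. Under that threshold 88 genes were higher and 75 lower. With each library left out, the counts ranged from 641 to 993 higher and 706 to 1164 lower. They were 644, 641 and 658 higher without sgNSD3 replicates 1, 2 and 3, and 989, 758 and 993 higher without sgControl replicates 1, 2 and 3, so the number of samples alone does not account for the drop. Of the 2169 called genes, 1305 stayed called in the same direction without sgNSD3 replicate 1, 1332 without replicate 2 and 1380 without replicate 3. Of 109 named genes 27 lost their call when at least 1 library was left out, and 0 of the named genes changed direction. By voom on the recovered counts 2062 stayed called, and 968 genes were higher and 1135 lower.

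No list stayed called with an estimated correlation in camera (0 higher and 0 lower). Lists called higher numbered 1 on ranks and 1 without a mean-variance trend, and from 1 to 2 with each library left out. Lists called lower ranged from 5, without sgControl replicate 2, to 9 with each library left out. They numbered 11 with no filter and with library weights, 7 with a mean of at least 32 normalized counts, and 6 under quantile normalization and after the length correction. Without sgControl replicate 2, the FGFR and MAPK feedback, G2 and mitosis, heat shock, MHC class I and oxidative phosphorylation lists were no longer called. After the length correction the heat shock, MHC class I and oxidative phosphorylation lists were no longer called. Col1a1 came out at 0.00 under quantile normalization against a rise in the main test, since that method gives a gene of equal rank the same value in each library.

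Title and description numbers of the sgNSD3 libraries disagree, and same-numbered libraries did not deviate together: correlations were 0.045, 0.016 and -0.013 by title, and -0.066, -0.007 and -0.04 by description. With a replicate block by title the counts were 1119 higher and 1333 lower, with 2 lists higher and 10 lower. With a replicate block by description they were 920 and 1087, with 2 and 9 lists. In both paired fits Nsd3 was at 0.57.

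Spearman's rho of H3K36me2 against RNA was 0.005 for genes above the median RNA level and 0.008 for sample 2 alone. Against H3K27me3 it was -0.11 and -0.12 for samples 1 and 2 alone, -0.029 for genes with tested RNA and -0.026 for those above the median RNA level. The cause of these differences was not tested. The alternatives for H3K36me2 and H3K27me3 between conditions (pseudocount, filter, normalization, IgG subtraction, block, libraries left out, and level filters) were not run, since the scores hold no values per library. Depth limits the low genes: folds of genes under about 32 normalized counts, such as Phf19, rest on few reads.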

Other observations

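The 2 tests of gene length and the count of splits were set before their results were seen, and the tests on Nsd3 and on chromosomes were chosen afterwards. Immune and endothelial markers were sparse, and many epithelial, squamous and lung markers were too. Of 24 general epithelial markers 10 passed the filter, of 26 squamous and basal markers 12, and of 22 lung markers 10. The highest were Krt19, Cd44 and Pdpn, at means of 3300, 4160 and 4650 normalized counts. Epcam was at 0 in both conditions. Means in sgControl and sgNSD3 were 3.38 and 3.25 for Cdh1, 1.04 and 3.97 for Trp63, and 0.349 and 0.321 for Nkx2-1. Of 18 immune markers 4 passed the filter, the highest being Csf1r at a mean of 167 normalized counts, and of 12 endothelial markers 4 passed, the highest being Kdr at 153. Kdr rose 1.66-fold and Esam was 1.34-fold lower, a call lost without any library but sgControl replicate 3. Of 10 general epithelial markers 1 rose and 2 fell (1.3-fold for Krt18, 1.46-fold for Krt19), of 12 squamous and basal markers 3 fell (Krt14 1.59-fold, Krt15 1.82-fold, a call lost on leaving out any 1 of 4 libraries, and Itga6 1.23-fold), with 2 and 2, and 0 and 3, rising and falling when adjusted over the list alone, and neither list was called (camera adjusted p = 0.89 and 0.46). Of 8 fibroblast markers 3 fell, with Mfap5 1.85-fold and Cd34 1.22-fold lower (also 3 when adjusted over the list alone; camera adjusted p = 0.061). Of 10 lung markers 1 rose and 2 fell (2 and 2 when adjusted over the list alone; camera adjusted p = 0.56), and of 23 interferon response genes 2 fell, among them Parp14 1.32-fold (4 when adjusted over the list alone; camera adjusted p = 0.72).

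Of 27 other developmental transcription factors 3 fell: Pax2 3.74-fold, from 40.9 ± 6.35 to 10.95 ± 4.01 normalized counts (SD, n = 3), Isl1 2.66-fold and Tbx3 1.24-fold (also 3 when adjusted over the list alone; camera adjusted p = 0.48). Of 29 HOX genes 3 rose and 1 fell (3 and 2 when adjusted over the list alone; camera adjusted p = 0.77), with Hoxc5 1.43-fold higher and Hoxb13 1.86-fold lower; Hoxc5 lost its call without sgControl replicate 2 or sgNSD3 replicate 2, and Hoxb13 without sgControl replicate 2 or sgNSD3 replicate 1. In the authors' deposited table the 38 HOX gene bodies had a median H3K27me3 score of -0.0913, with 36 below 0. Of 10000 random lists of the same size, 0% had a median as low, a comparison added after the values were seen and not matched on expression. It was made for every list and both marks, and HOX genes were not alone. For the 53 other developmental transcription factors (median -0.0516, 37 below 0) the share was 0.01%. For the mean H3K36me2 score, 100% of random lists lay at or below the fibroblast list and 99.9% at or below the inflammatory list. Random lists took genes singly, whereas HOX genes such as Hoxa4 and Hoxa5 are neighbours, so the 0% can overstate how rare the median is.

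Nsd3 RNA was 1.51-fold higher in the libraries labelled sgNSD3. A gain of the surrounding region is argued against, since the median log2 change of the other 25 tested genes within 1 Mb was 0.005. Of these 25 genes, 4 were called higher and 1 lower, against 993 higher and 1176 lower of all 18278 tested genes. Among the 4 were Gm16159 at a log2 fold of 0.61 (limma adjusted p = 0.0307) and Tacc1 at 0.34. The median therefore speaks to the region as a whole and not to each gene in it. Library scaling is argued against as well: before any scaling the log2 ratio of mean Nsd3 counts was 0.615, the lowest count labelled sgNSD3 being 21277 and the highest sgControl count 15050, while that of the library totals was 0.024. An exchange of the labels of the conditions stays open: 0 rows of the RNA table were named for a vector or editing sequence, so no other value marks the edited cells. A response of the gene to its own edit was not tested.

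Long genes tended to be higher and short ones lower. With genes in 5 bins of length, 422 of the 3100 longest were higher and 210 lower, and 54 of the 3100 shortest were higher and 239 lower. Length was the span of the gene in the genome. After a length trend was removed from each library, 86.8% of the called genes with a known length stayed called in the same direction. Such a trend was small: the 5 bins had median log2 folds from -0.036 to 0.028. Among called genes the median absolute log2 fold was 0.26. Most calls could therefore outlast the correction, which cannot decide what caused the length pattern. A contribution of length bias stays open: Spearman's rho of length with the RNA change was 0.137, and within the sgControl libraries a deviation of one library from its own condition reached 0.155 in size. A biological effect on long genes may add to this and was not separated from it.

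Chromosome medians of the H3K36me2 columns in the authors' deposited table moved together (Pearson r = 0.96 over 19 autosomes and X, Spearman's rho = 0.94, permutation p = 1e-05 each, the smallest that 100000 resamples give, adjusted p = 3e-05 over 6 relations). Without the 2 chromosomes farthest from the median of sample 1, which were X and 7, r was 0.91. Over the 19 autosomes alone r was 0.93. With the H3K27me3 medians r was -0.6 and -0.61 (adjusted p = 0.0094 each) and Spearman's rho -0.63 and -0.6 (adjusted p = 0.007 and 0.0084). Over the autosomes alone r was -0.42 and -0.44 (adjusted p = 0.074 and 0.067) and rho -0.57 and -0.53 (adjusted p = 0.014 and 0.02), so the relation passed the threshold there on ranks only. Without the 2 farthest chromosomes r with H3K27me3 was -0.4 and -0.45, and -0.31 and -0.44 over the autosomes. At the digits given, several chromosomes shared a median. The H3K36me2 sample 2 median was 0.134 on chromosomes 8, 10, 13, 16 and 17. The H3K27me3 median was -0.0258 on chromosomes 4, 12, 13, 16 and 17. The medians are thus coarse, which limits what these correlations can show. In the authors' deposited table the X medians were 0.0388 and 0.0716 for H3K36me2, against 0.0773 and 0.132 over the autosomes, and -0.00395 against -0.0264 for H3K27me3. These are signed scores with an unknown zero, so their ratios have no meaning as copies of DNA. Chromosomes are not replicates, and the header does not say whether the columns share a library. These p-values therefore do not measure how well a mark repeats between libraries. Across 21995 gene bodies Spearman's rho between the H3K36me2 columns was 0.18. Neither a technical nor a biological explanation was tested.

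Of the 10 splits of the 6 RNA libraries into 3 and 3, 1 gave 2169 or more called genes, namely the real one, and the highest of the others gave 0. With 10 splits no share under 0.05 can be reached.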
